A study of Mus musculus with 1248 samples.

How the data were processed

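Full-length RNA libraries of single sorted cells were made with a modified Smart-seq2 protocol from oligo-dT primed RNA and sequenced on an Illumina HiSeq X instrument with paired 150-base reads, per the labels. The authors deposited 1 table of counts with a column per cell, and these are whole-number read counts per gene symbol, not molecules. The submitters' processing notes name build mm10 and the tools FastQC 0.11.7, Trim Galore 0.6.6, STAR 2.6.0c, SAMtools 1.7, featureCounts 1.6.2, R 3.6.2 and Seurat 3.1.2, without the role of each, and the gene annotation is not given in the sources used here. Per the labels, wells were discarded when qPCR of mCherry gave a Ct above 30. The table held 40840 entries: 40756 genes, 78 ERCC spike-in sequences, the reporters mCherry and luciGFP, and 4 repeated date-like symbols, which were left out and held 0.0149% of counts. ERCC and reporter entries held 0.670% and 0.187% of counts and stayed out of library sizes. No pair of cells held identical values.

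Each of the 1248 cells was put in 1 of 7 groups from its own label by line, day and site. A cell passed with at least 1000 detected genes, at least 50000 counts in genes and at most 25% of them mitochondrial, which 1218 did. The lowest total of any cell was 44 counts. Median totals per cell were 2981083 counts in 4T1 culture, 3031687 at day 4, 3023738 at day 10, 2647148 at day 16, 2966625 in the fat pad, 3054736 in 4T1.2 culture and 2783143 in 4T1.2 at day 4. Summed over tumour cells the groups held, in the same order, 162200680, 449457991, 154040462, 228658484, 242154012, 176172880 and 155683958 counts, with the widest counting interval of a value of 20 CPM or more given in the text below.

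Cells were scaled to their total, log-transformed and clustered with scanpy 1.11.5, leidenalg 0.10.2 and igraph 0.11.9 on 2000 variable genes, 20 principal components, 15 neighbours and resolution 1, which gave 17 clusters. A cluster was named from fixed markers of 14 cell classes when at least 3 markers of a class had a median of 50 CPM or more and stood at least 1 log2 unit above the other clusters. A host class also needed more than 1 marker among the cluster's 15 leading genes. Where several classes qualified, the class with most markers among the 10 leading genes was taken. A cluster also led by markers of another host class got no single class. It was named pan-haematopoietic where at least 3 of those markers qualified. The markers were fixed before the data were examined, but this naming rule was settled after the clusters were seen, and the earlier rules are among the alternatives. Clusters of host classes, 10 in number, left the sums. The 6 clusters named as tumour and 1 unnamed cluster stayed.

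Counts of tumour cells were summed per group and scaled to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0 did the other steps, and matplotlib 3.10.9 drew the figures. Ratios are log2 of CPM plus 5, and no fold is given for a group without a count. CPM carry exact Poisson intervals and shares of cells exact binomial intervals, both at 95%. Detection shares were taken after thinning each cell to 500000 counts, the deepest of 50000, 100000, 200000 and 500000 that kept at least 80% of cells in every group. Thinning left out 4 cells of 4T1 day 4, 2 of day 10, 2 of day 16, 1 each of the fat pad, 4T1 culture and 4T1.2 day 4, and none of 4T1.2 culture.

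The 8 comparisons, the 20 gene lists, the cell filter and the rule for naming genes were written before the data were examined. No test was made, because no animal, plate or culture is named and a test across cells would count cells of 1 sample as replicates. Named genes are the 12 furthest higher and the 12 furthest lower in a comparison among genes with at least 20 CPM and detection in at least 30% of thinned cells of the higher group, and at least 2-fold apart in the same direction with cells weighted equally. For lists, 2 to 4 members furthest in the list's direction and up to 2 members against it may be named. A list member needed 5 CPM in either group, and the percentile of a list's median came from 10000 random lists drawn within 20 bins of mean expression. A list stood apart below the 2.5 or above the 97.5 percentile. Positions are from GENCODE M21. Some genes that this rule picks are not reported here.

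The steps were tested on simulated data shaped like 4T1 day 4 against culture, with 6857 genes. Planted log2 ratios of 2, 1, −1 and −2 came back as medians of 1.94, 0.84, −0.90 and −1.70 over 50 genes each, and 2 of 6638 unchanged genes passed 2-fold. Of 200 random lists without change 3 stood apart, and a list of 30 genes planted at 1.5-fold had a median of 0.45. Simulated genes varied independently around the culture profile, without plates or animals. The rate among random lists therefore does not cover lists of co-regulated genes.

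Alternatives were totals without TMM, DESeq2 1.42.0 size factors, cells weighted equally, summed thinned cells, no cell filter, a stricter filter (2500 genes, 200000 counts, 15% mitochondrial), host-like cells included, cells with any Ptprc count left out, pseudocounts of 1 and 20 CPM, no minimum on list members, the lower-numbered or the higher-numbered cells of each group, and resolutions of 0.5 and 2. Added after the data were examined were wells with at least 300 CPM over 10 pan-haematopoietic genes left out (mixed wells), the same with cross-talk subtracted, and other rules for host-like cells. Cross-talk was estimated per group as the median percentage of the group's mean profile at which host markers appeared in unmixed tumour cells, 1.34% at 4T1 day 4.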

Results

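Single cells of the mouse mammary carcinoma line 4T1 and its derivative 4T1.2 were measured by full-length RNA sequencing. Both lines carried firefly luciferase and mCherry, and mCherry-positive cells were sorted from the hindlimbs of female BALB/c mice at day 4, 10 or 16 after intracardiac injection. Cultured cells of both lines and 4T1 cells of a mammary fat pad tumour at day 22 served as the reference groups. Counts of 1248 cells were read, and 1218 of them passed the filter: 54 of 4T1 culture, 496 of 4T1 day 4 bone, 95 of 4T1 day 10 bone, 190 of 4T1 day 16 bone, 95 of the fat pad, 53 of 4T1.2 culture and 235 of 4T1.2 day 4 bone. The median cell held between 2647148 counts at day 16 and 3054736 in 4T1.2 culture, and between 9550.5 and 11372 detected genes. No animal, plate or culture was named for any cell, so each group was treated as 1 sample and no difference below was tested across animals. Intervals cover counting error only, and these libraries carried no molecular barcodes. Levels are scaled counts (CPM), and at 20 CPM or more in summed cells the 95% interval reached at most 3.66% above and 3.56% below the value.

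The first question was which cells the sequenced wells held. Wells with an mCherry Ct above 30 had been discarded, so shares below are of kept wells, not of all sorted cells. S100a8 and Ngp, granule and calcium-binding proteins of neutrophils, reached means of 74761 and 45975 CPM in 169 cells. Lyz2, the lysozyme of myeloid cells, averaged 14274 CPM in 180 cells named as monocytes or macrophages, which joined 2 clusters. C1qa, a complement subunit of tissue macrophages, stood at 3682 CPM in the 100 cells of the first and 9.70 CPM in the 80 cells of the second, where Mpo, a granule enzyme of myeloid precursors, stood at 4145 CPM. The haemoglobin genes Hbb-bs and Hba-a1 averaged 16163 and 15278 CPM in 64 erythroid cells, and Ighm and Cd79a, parts of the B-cell receptor, 5237 and 1813 CPM in 145 B cells. Gzma and Nkg7, granule proteins of cytotoxic lymphocytes, averaged 2039 and 1088 CPM in 21 cells. In total 710 cells lay in clusters with host markers and 508 in clusters treated as tumour cells, which included 1 cluster of 99 cells that no marker set named but in which Krt8 and Krt18, the keratins of simple epithelia, were high. That cluster held 96 of the 140 tumour cells of 4T1 bone at day 4, and its median luciGFP was 57.8 CPM there.

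Groups are named by the injected line, so host-like cells are counted among the 4T1 or 4T1.2 cells of which a share is given. Host-like cells made up 71.8% (95% CI 67.6 to 75.7) of 4T1 cells from bone at day 4, 44.2% (34.0 to 54.8) at day 10 and 63.2% (55.9 to 70.03) at day 16. Among 4T1.2 cells from bone at day 4 the share was 77.4% (71.6 to 82.6), and in the fat pad 10.5% (5.16 to 18.5). No cultured cell was host-like, with upper limits of 6.60% for 4T1 and 6.72% for 4T1.2. B cells made up 21.0% (17.5 to 24.8) of 4T1 cells at day 4 and 2.11% at day 16, whereas monocytes and macrophages made up 13.1% (10.3 to 16.4) at day 4, 25.3% (16.9 to 35.2) at day 10 and 36.3% (29.5 to 43.6) at day 16. Of these cells 53 of 65 at day 4 belonged to the Mpo cluster and 60 of 69 at day 16 to the C1qa cluster, so the shares do not follow 1 population. The B-cell class also joined different clusters. The cluster led by Igll1 and Vpreb1 held 52 cells of 4T1 at day 4 and 0 at day 16. The cluster led by Ighm and Cd79a held 52 and 4. Neutrophils stood at 19.8% (16.3 to 23.5), 12.6% (6.70 to 21.0) and 21.1% (15.5 to 27.5). In 4T1.2 at day 4 B cells made up 15.7% (11.3 to 21.0), erythroid cells 13.6% (9.50 to 18.7), neutrophils 8.09% (4.94 to 12.3) and monocytes or macrophages 5.11% (2.67 to 8.75), with 11 of these 12 cells in the Mpo cluster. T and NK cells made up 1.01% in 4T1 and 2.98% in 4T1.2 at day 4. A class of 131 cells was named by pan-haematopoietic markers, of which Rac2, a blood-cell GTPase, was the most abundant. It made up 10.7% (8.11 to 13.7) of 4T1 and 31.9% of 4T1.2 cells at day 4. Its larger cluster of 110 cells held B-cell and neutrophil genes, among them Cd79a and S100a9. There 8 B-cell and 10 neutrophil markers had a median of 50 CPM or more. Whether these wells held RNA of more than 1 cell was not tested. The basophil gene Prss34 was present too, but no basophil marker met the naming rule there. The smaller cluster of 21 cells was led by Siglech and Cd7. These cells are not counted in the B-cell and neutrophil shares.

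**Figure D1:**
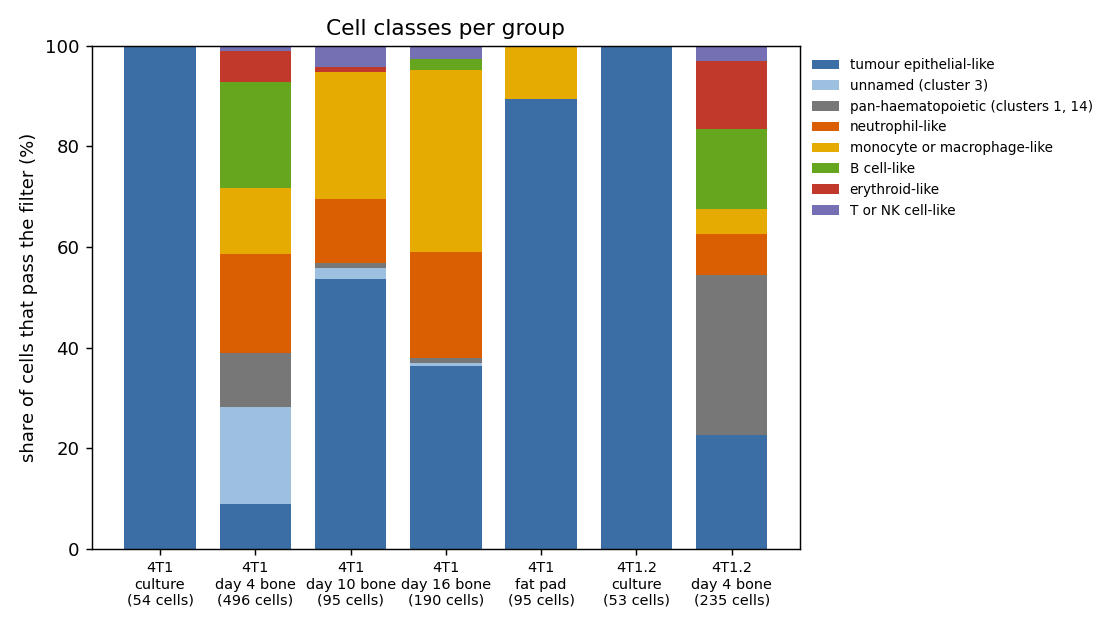
Share of passing cells in each cell class, in percent of the group, for the 7 groups. The joined monocyte and macrophage class was 13.1% of 4T1 cells from bone at day 4, where 53 of 65 were of the Mpo cluster, and 36.3% at day 16, where 60 of 69 were of the C1qa cluster.

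The mCherry transcript, the reporter used for the sort, was present in host-like as well as tumour cells. Wells had also been kept by mCherry qPCR, so sequenced wells were selected for mCherry RNA. Its median was 1920 CPM in host-like and 415 CPM in tumour cells of 4T1 at day 4, and 206 and 337 CPM in 4T1.2 at day 4. The other reporter entry, luciGFP, stood at 0.617 CPM in host-like and 60.1 CPM in tumour cells of 4T1 at day 4. Krt8 and Krt18 together stood at 14.4 CPM in host-like and 3512 CPM in tumour cells. By class, B cells of 4T1 at day 4 held a median of 3434 CPM of mCherry and neutrophils 2036 CPM. In 4T1.2 at day 4 B cells held 2380.2 CPM, but neutrophils 30.8 and erythroid cells 41.3 CPM. At day 16 neutrophils held 2672 CPM but monocytes and macrophages 32.6 CPM. In the fat pad the host-like cells held 13.2 CPM of mCherry and the tumour cells 594 CPM. Summed over tumour cells mCherry lay between 403 CPM in 4T1.2 at day 4 and 1079 CPM in 4T1 at day 16, and luciGFP between 40.4 CPM in 4T1 culture and 159 CPM in 4T1 at day 4.

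**Figure D2:**
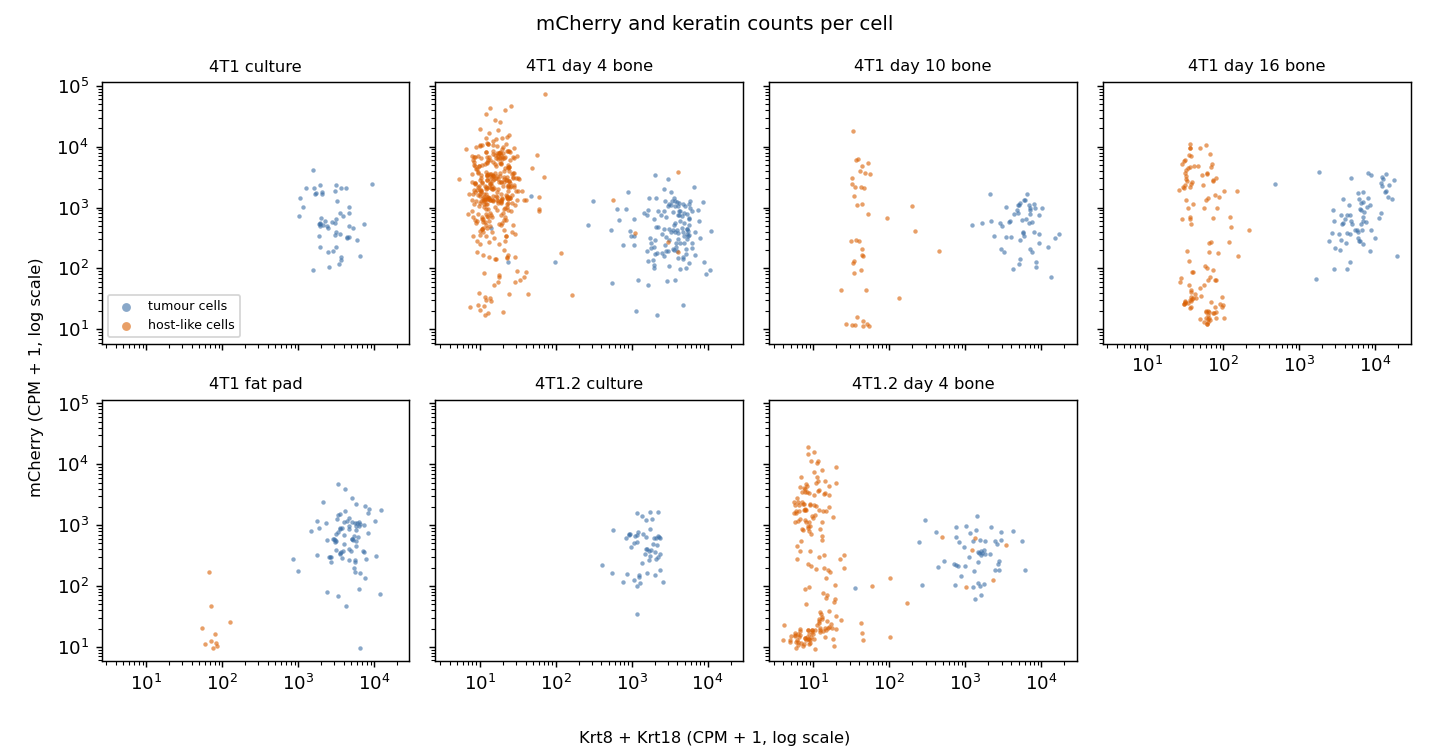
mCherry against the sum of Krt8 and Krt18 of each cell, in CPM on log axes, by group, with host-like and tumour cells coloured apart. Host-like cells of 4T1 at day 4 had a median of 1920 CPM of mCherry but 14.4 CPM of Krt8 and Krt18.

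The comparisons below used tumour cells alone: 54 of 4T1 culture, 140 of 4T1 bone at day 4, 53 at day 10, 70 at day 16, 85 of the fat pad, 53 of 4T1.2 culture and 53 of 4T1.2 bone at day 4. Genes of blood cells remained in these sums, and 63 tumour wells also held at least 300 CPM over 10 pan-haematopoietic genes. Of these wells 30 lay in 4T1.2 at day 4 and 15 in 4T1 at day 4. Ratios are log2 of the group named first over the group named second, with 5 CPM added to both, and 20 gene lists written before the data were examined were followed in each comparison. A list stood apart when its median lay outside the middle 95% of 10000 random lists of matched expression. The median log2 ratio of all genes was −0.11 for 4T1.2 at day 4 against culture.

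**Figure D3:**
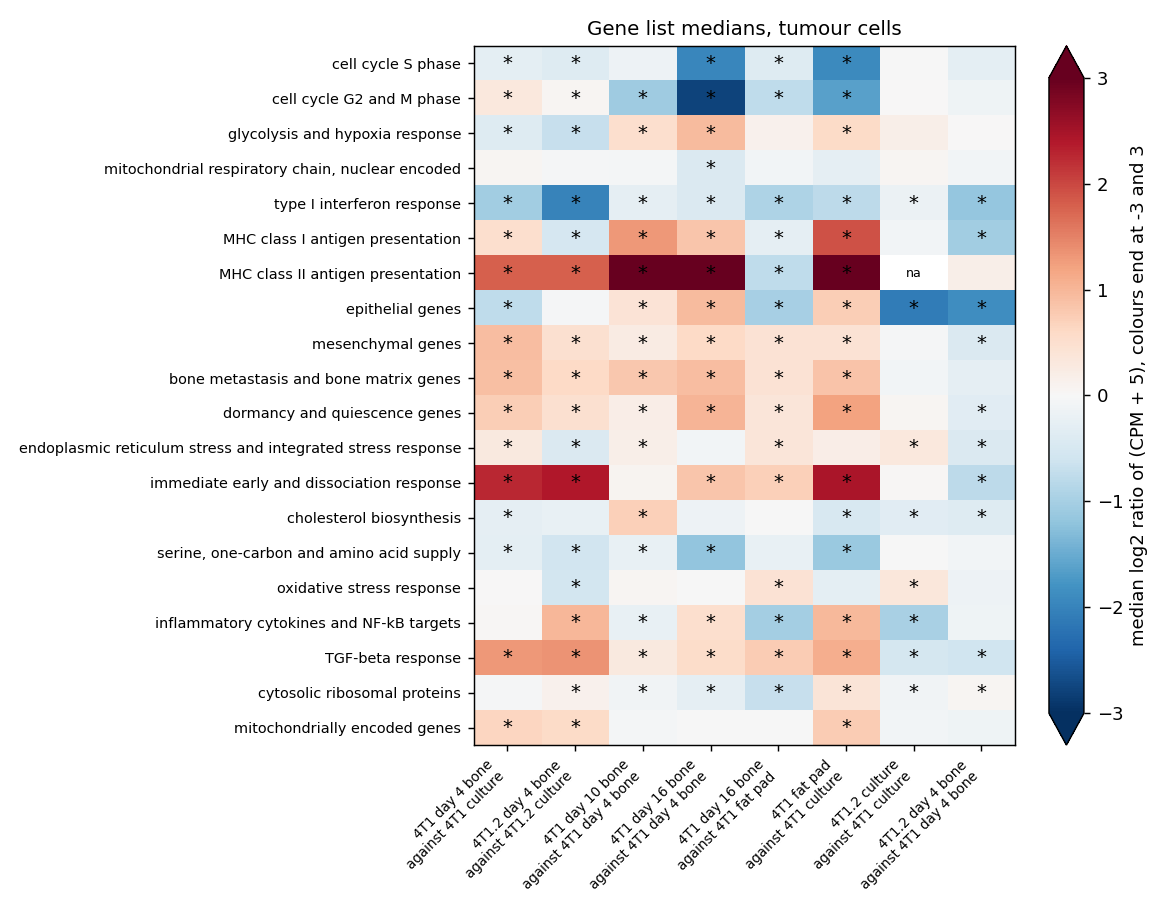
Median log2 ratio of each gene list in the 8 comparisons of tumour cells, with lists that stood apart from random lists marked. The immediate early list had medians of 2.27 and 2.40 for day 4 bone against culture in 4T1 and 4T1.2.

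4T1 cells in bone at day 4 were set against cultured 4T1, which asks how tumour cells recovered early from bone differed from the injected line. Fos, a subunit of the AP-1 transcription factor on chromosome 12 (85473890 to 85477273, build mm10), stood at 6936 CPM (6928 to 6944) in bone and 17.6 CPM (17.0 to 18.2) in culture. The nuclear receptors Nr4a1 and Nr4a2 stood at 1495 and 442 CPM against 8.52 and 3.20. Cxcl5, which attracts neutrophils, and Il1a, an alarm cytokine, were at 7.68 and 4.42 CPM in bone against 279.96 and 167 in culture. Cdh1 and Cldn3, adhesion and tight junction proteins of epithelium, were at 46.9 and 21.3 CPM against 238 and 193.

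The immediate early list, whose genes answer growth signals and also tissue dissociation, had a median log2 ratio of 2.27, with 27 of 34 members at least 2-fold higher. Fosb and Dusp1, a MAP kinase phosphatase, had log2 ratios of 5.50 and 4.97, while Myc lay the other way at 279 CPM in bone and 608 in culture. TGF-beta response genes had a median of 1.30, led by the inhibitor of differentiation genes Id2, Id1 and Id3 at 217, 661 and 887 CPM against 29.1, 132 and 188. Mesenchymal genes stood at 0.92, with the collagen gene Col6a1 at 124 CPM against 9.72 and the matrix protease Mmp3 at 257 against 30.5. Thbs1, a matrix glycoprotein in both the mesenchymal and the TGF-beta list, was lower at 102 CPM against 505. Bone matrix and metastasis genes had a median of 0.91: the osteopontin gene Spp1 stood at 2329 CPM against 579.8, the gelatinase Mmp9 at 801 against 90.1, and Pthlh, the PTH-related hormone that drives bone resorption, at 48.4 against 7.01. Ctgf, a connective tissue factor that is also in the TGF-beta list, ran the other way at 33.2 against 177 CPM. The dormancy list stood at 0.75, with Klf4 at 119 CPM against 3.26 and the cell cycle inhibitor Cdkn1a at 160.4 against 27.0. Klf4 is also in the immediate early list, so these lists are not independent.

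Type I interferon genes had a median of −1.04, and 22 of 42 were at least 2-fold lower in bone. Bst2, which tethers virus particles, and the regulator Irf7 stood at 143 and 89.3 CPM against 602 and 338. MHC class I genes had a median of 0.51, with the immunoproteasome subunit Psmb9 at 92.3 CPM against 38.4. MHC class II genes stood at 1.80 over 7 members and between 0.67 and 3.74 over planned settings. H2-Aa and H2-Ab1 reached only 21.1 and 18.4 CPM, with no count in culture. The median of tumour cells for H2-Ab1, 2.84 CPM, lay below the 5.46 CPM of host-like cells. For Cd74, the class II invariant chain gene, the tumour median of 8.51 CPM lay above the host-like median of 6.05 CPM. Epithelial genes stood at −0.77, with Cldn4, another tight junction gene, at 20.3 CPM against 102. The integrin Itgb4 was an exception at 168 against 52.8. S phase genes had a median of −0.30 and G2 and M phase genes of 0.32, with Exo1 at 28.8 against 63.9 CPM and Ccnb1, the mitotic cyclin, at 345 against 183. Glycolysis and hypoxia genes stood at −0.40, cholesterol synthesis at −0.28, serine and amino acid supply at −0.30 and integrated stress response genes at 0.30. In these lists Pdk1, which inhibits pyruvate dehydrogenase, was at 8.50 CPM against 36.5, the desaturase Scd1 at 6.89 against 22.8, the serine enzyme Psat1 at 313 against 533 and the stress gene Ppp1r15a at 215 against 15.8. Mitochondrially encoded genes stood at 0.65, whereas the nuclear respiratory chain (0.05), oxidative stress (0.01), inflammatory (0.03) and ribosomal protein (−0.04) lists did not stand apart. Of 12 planned settings the S phase, G2 and M phase, mesenchymal, bone and integrated stress response lists stood apart in 11 and the mitochondrially encoded list in 10, with G2 and M phase at 0.10 when cells were weighted equally. With mixed wells left out and cross-talk subtracted, only 19 of 20 lists kept enough members to be measured, 9 of them higher and 7 lower.

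Among the 12 genes furthest higher in bone, 5 were host genes: S100a9, Ngp, S100a8, Lyz2 and Camp, between 191 and 847 CPM. With wells holding blood-cell RNA left out and cross-talk subtracted, S100a9 went from a log2 ratio of 6.64 to 0.54 and Lyz2 from 5.61 to 1.02. Both are host markers from which the subtracted share was estimated, so their fall follows from the method. Fos kept 8.27 and Nr4a1 6.81. Dusp2 of the immediate early list and Btg2 of the dormancy list completed the higher genes with Nr4a2, at 5.60 and 4.54. The lower genes also held Serpinb2, a protease inhibitor, at 0.0940 against 65.4 CPM, Wnt7a, a secreted ligand, at 3.92 against 75.5, and Oas3, an interferon gene, at 17.9 against 120.1. Mal, Mirt1, Mmp10, H2-M2 and Cyp1b1 were lower too, with log2 ratios between −3.34 and −2.47. Serpinb2, Mmp10 and H2-M2 were under 5 CPM in the median cell of both groups, so a minority of cultured cells carried their sums.

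4T1.2 cells in bone at day 4 against cultured 4T1.2 asked whether the derivative line differed from its culture in the same genes. Fos stood at 2533 CPM against 8.23, Fosb at 428 against 8.28 and Nr4a1 at 599 against 23.7. Ifi44 and Usp18, both induced by interferon, were at 17.0 and 14.3 CPM in bone against 514 and 294 in culture. B2m, the light chain of every MHC class I molecule, was at 1006 CPM against 3060.2. Ndrg1, a hypoxia-induced gene, was at 10.2 CPM against 151, and the glucose transporter gene Slc2a1 at 113 against 371.

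The immediate early list had a median of 2.40, TGF-beta response 1.35, mesenchymal genes 0.49, bone genes 0.60 and dormancy genes 0.48, all higher in bone. Smad7, which TGF-beta induces as its own brake, stood at 72.6 CPM against 6.96, and Mmp9 at 857 against 48.9, while the collagenase Mmp13 was lower at 0.907 against 30.2. Type I interferon genes stood at −2.01, with 37 of 42 members at least 2-fold lower. MHC class I genes stood at −0.51, against 0.51 in 4T1, with H2-T23 at 29.7 against 132 CPM but Irf1 higher at 209 against 46.3. Integrated stress response genes stood at −0.43, against 0.30 in 4T1, with Chac1, a glutathione-degrading enzyme of that response, at 12.3 against 79.4 CPM. Glycolysis and hypoxia genes (−0.69), oxidative stress genes (−0.56), serine supply (−0.57) and S phase genes (−0.38) were lower. Nqo1, a quinone reductase of the oxidative stress list, stood at 19.2 against 128 CPM, the glycine transporter gene Slc6a9 at 0.821 against 18.8 and Cdc6, which loads replication origins, at 81.3 against 162. The inflammatory list was higher at 0.99, with Nfkbia, the NF-kB inhibitor, at 533 against 95.7 CPM, and its median was 0.49 without the 30 mixed wells. MHC class II genes had a median of 1.80, between 0.73 and 3.58 over planned settings, but fewer members than needed remained without mixed wells, and Cd74, the invariant chain, went from a log2 ratio of 3.00 to 0.15 after subtraction. G2 and M phase (0.07), ribosomal protein (0.13) and mitochondrially encoded (0.57) lists were higher, but the G2 and M phase median was −0.10 in lower-numbered cells and −0.0408 without a cell filter, and the ribosomal protein median −0.21 with host-like cells included. The respiratory chain (−0.04), epithelial (−0.04) and cholesterol (−0.22) lists did not stand apart. MHC class I genes stood apart in 10 of 12 planned settings and not in higher-numbered cells, at −0.41; S phase, G2 and M phase, mesenchymal, bone, dormancy, oxidative stress, inflammatory, ribosomal protein and mitochondrially encoded lists did in 11.

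Across 7792 genes the log2 ratios of day 4 bone against culture in the lines had a Pearson r of 0.583 and a Spearman rho of 0.472, where genes are not independent replicates. At least 2-fold higher in bone were 541 genes of 4T1 and 403 of 4T1.2, with 219 shared where 28.0 would be shared if the sets were independent. At least 2-fold lower were 202 and 331 genes, with 84 shared against 8.58, and 18 genes lay in opposite directions. With mixed wells left out and cross-talk subtracted, 412 and 241 genes were higher with 110 shared against 13.0, 89 lower genes were shared against 11.1, and r was 0.506.

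4T1 bone at day 10 against day 4 asked what differed between seeding and progression. The MHC class II genes H2-Ab1 and H2-Eb1, which present antigen to helper T cells, lie on chromosome 17 (34257689 to 34269419 and 34305867 to 34316674) and stood at 985 CPM (980.2 to 991) and 722 CPM against 18.4 and 12.4. Spp1 stood at 8499.7 CPM against 2329, Pthlh at 319 against 48.4 and Mmp13, which cuts bone collagen, at 59.9 against 3.89. Car9, the carbonic anhydrase of hypoxic cells, was at 105 CPM against 16.0. The mitotic genes Ube2c, Aurka and Plk1 were at 116, 59.2 and 51.7 CPM against 476, 212 and 184.

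MHC class II genes had a median of 4.35 and MHC class I genes of 1.30, with 17 of 22 class I members at least 2-fold higher. Without mixed wells the class II median was 4.71, and the median tumour cell held 529 CPM of H2-Ab1. Bone genes stood at 0.80, although Mmp9 was lower at 301 against 801 CPM. Cholesterol synthesis stood at 0.71, with Insig1, a sterol sensor, at 102 against 22.1 CPM, and glycolysis and hypoxia at 0.50. Epithelial genes stood at 0.41, with the protease gene St14 at 155 against 43.8 CPM, while the basal keratin gene Krt14 was lower at 35.6 against 223. TGF-beta response (0.29), mesenchymal (0.24), dormancy (0.19) and integrated stress response (0.18) lists were higher, with Thbs1 at 387 against 102 CPM, Sox9, a progenitor transcription factor, at 1210.2 against 456 and Xbp1, a regulator of protein folding, at 373 against 147. G2 and M phase genes stood at −1.07, with 20 of 38 at least 2-fold lower, whereas S phase genes at −0.15 did not stand apart. Interferon genes stood at −0.28, with the antiviral gene Cmpk2 at 33.6 against 137 CPM, and inflammatory genes at −0.23, with the chemokine Cxcl1 at 77.5 against 307. Ribosomal protein (−0.11) and serine supply (−0.22) lists were lower too, and the immediate early list (0.09) did not stand apart. Dormancy and serine supply lists stood apart in only 7 of 12 planned settings and inflammatory and ribosomal protein lists in 8, with dormancy at −0.0318 and ribosomal protein at 0.05 in lower-numbered cells, while interferon, mesenchymal, bone and integrated stress response lists did in 11. Krt14, Cmpk2 and Mmp13 were under 5 CPM in the median tumour cell of both groups, Krt14 at 0.301 at day 10 and 1.18 at day 4, so a minority of cells carried their sums.

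4T1 bone at day 16 against day 4 carried the same question to the late stage. Spp1, on chromosome 5 (104435118 to 104441050), stood at 23583 CPM (23562 to 23603) against 2329 CPM (2324 to 2333). Cd74 stood at 1769 CPM against 58.6, and H2-Eb1 at 656 against 12.4. Dmp1, a matrix protein of osteocytes and bone mineral, stood at 412 CPM against 19.4, and Fn1, fibronectin, at 3149 against 394. Car9, on chromosome 4 (43506966 to 43513729), was at 443 CPM against 16.0. The mitotic genes Plk1 and Ccnb1 were at 9.25 and 25.4 CPM against 184 and 345, and Rrm2, which makes deoxynucleotides, at 33.8 against 401. Day 10 lay in between for Spp1 at 8499.7 CPM, Cd74 at 1581, Dmp1 at 212, Car9 at 105, Plk1 at 51.7 and Rrm2 at 346 CPM. It did not for H2-Eb1, which was higher at day 10 than at day 16.

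All 38 measured G2 and M phase genes were at least 2-fold lower at day 16, with a median of −2.77. S phase genes had a median of −1.96, with 29 of 35 at least 2-fold lower, among them the replication helicase gene Mcm5 at 42.9 against 384 CPM. Serine supply stood at −1.19, where Psat1, on chromosome 19 (15904678 to 15947337), was at 17.2 CPM against 313 and the folate enzyme Shmt1 at 8.99 against 87.2. Interferon genes (−0.44), the respiratory chain (−0.44) and ribosomal proteins (−0.26) were lower, with Oasl1 at 6.88 against 80.9 CPM, cytochrome c (Cycs) at 58.5 against 175 and Rps2 at 377 against 832. MHC class II genes stood at 4.14 and at 4.64 with mixed wells out and cross-talk subtracted. The median tumour cell held 545 CPM of H2-Ab1 and the median host-like cell 113 CPM. MHC class I genes stood at 0.82, with H2-D1 at 9967 against 3481 CPM. Dormancy (1.02), glycolysis and hypoxia (0.95), bone (0.93), immediate early (0.84), mesenchymal (0.59), TGF-beta (0.55) and inflammatory (0.50) lists were higher. Among their members the LIF receptor gene Lifr stood at 43.8 against 4.69 CPM, the glycolytic switch gene Pfkfb3 at 58.1 against 7.88, Junb at 7305 against 2518 and Ltbp3, which stores TGF-beta in matrix, at 492 against 117. Of 12 planned settings the inflammatory list stood apart in 9, bone and ribosomal protein lists in 10, and mesenchymal and epithelial lists in 11.

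Epithelial genes had a median of 0.94 at day 16, with Epcam at 849 CPM against 68.3 and the tight junction gene Cldn4 at 602 against 20.3. These genes were high in 23 day 16 cells of 1 cluster, all of them among the lower-numbered cells of the group. The epithelial median was 1.10 in lower-numbered and 0.01 in higher-numbered cells, and per cell the sum of Epcam and Cldn4 had medians of 2377 and 1.51 CPM. Cldn4 was detected in 63.2% of day 16 cells and 12.5% of day 4 cells at equal depth. Without thinning it was also detected in 45.8% of host-like cells at day 16 and 16.3% at day 4, where its median was 0 CPM in both. The other higher genes were Moxd1, a monooxygenase-like protein, Cp, ceruloplasmin, Wisp2, a matricellular protein, and the class II genes H2-DMb1, H2-DMb2, H2-Ab1 and H2-Aa, with log2 ratios between 3.89 and 5.02. Further lower genes were the interferon-induced Rsad2 and Cxcl10, the protease Klk10, and Birc5, Ube2c and Rfc5 of the cell cycle, between −3.75 and −3.37. Rsad2, Cxcl10, Oasl1, Wisp2, Ccr7, Lifr and Pfkfb3 were under 5 CPM in the median tumour cell of both groups, so a minority of cells carried their sums. The sum of Rsad2, Ifit1 and Cxcl10 had medians of 7.03 CPM per cell at day 4 and 2.64 at day 16, and a cluster of 12 cells, 10 of them from day 4, was led by Cxcl10, Cxcl11 and Rsad2. Ccr7, a lymphocyte chemokine receptor at 47.8 CPM at day 4, went from a log2 ratio of −3.38 to −0.54 without mixed wells.

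4T1 bone at day 16 against the fat pad tumour asked what set late bone cells apart from the same line in the breast. Nr4a2, on chromosome 2 (57106830 to 57124003), stood at 927 CPM (923 to 931) in bone and 28.5 CPM (27.8 to 29.2) in the fat pad. Snai1, which represses epithelial genes, stood at 302 CPM against 56.5, and Sparc, a collagen-binding matrix protein, at 802 against 167. Pthlh was at 254 CPM against 51.5 and the osteoclast-stimulating cytokine gene Il11 at 38.4 against 2.71. Ccl2, which draws monocytes, was at 3.79 CPM against 166, Il1a at 9.66 against 232 and the nitric oxide synthase gene Nos2 at 0.775 against 70.6. Krt17, a keratin of stressed epithelium, had 1 count in bone and stood at 124 CPM in the fat pad.

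Epithelial genes had a median of −0.998, with Muc1 at 6.43 against 59.9 CPM and Elf3, an epithelial transcription factor, at 37.8 against 191, though Krt8 was at 4094 against 2759. Their median was −0.39 in lower-numbered and −1.90 in higher-numbered cells. Inflammatory genes stood at −1.02, with Cxcl10 at 19.6 against 191 CPM but the adhesion molecule gene Icam1 the other way at 105 against 10.2. Interferon (−0.94), MHC class II (−0.77) and class I (−0.27), G2 and M phase (−0.76), S phase (−0.38) and ribosomal protein (−0.70) lists were lower in bone. Usp18 stood at 24.9 against 155 CPM, Ciita, the master regulator of class II genes, at 9.29 against 43.4, Plk1 at 9.25 against 38.6 and Rps23 at 369.8 against 792. TGF-beta response (0.76), immediate early (0.70), mesenchymal (0.44), bone (0.44), oxidative stress (0.42), dormancy (0.37) and integrated stress response (0.36) lists were higher. Id1 stood at 354 against 82.3 CPM, the haem oxygenase gene Hmox1 at 155 against 34.3 and Cdkn1a at 211 against 33.6, while the bone sialoprotein gene Ibsp lay the other way at 9.90 against 98.0. The immediate early median was 1.22 in lower-numbered and 0.17 in higher-numbered cells. Of 12 planned settings mesenchymal genes stood apart in 8, S phase, integrated stress response and immediate early lists in 10, and only the interferon, epithelial, TGF-beta and ribosomal protein lists in all.

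Of the 12 genes furthest higher in bone at day 16 than in the fat pad, 10 were host genes: S100a8, Ngp, S100a9, Lyz2, Camp, Cd177, Retnlg, Mmp8, Hp and Ifitm6. S100a8 stood at 1605 CPM against 1.05, and its log2 ratio of 8.06 became −0.27 after mixed wells were left out and cross-talk was subtracted. The subtracted share was estimated from host markers, S100a8 among them, so this fall follows from the method. Nr4a2 and Plscr4, a phospholipid scramblase at 108 against 5.17 CPM, were the others. After that correction Id2, at 243 against 19.9 CPM, the stress gene Gadd45g, at 697 against 77.8, and Mgp, a brake on mineralization, at 1262 against 174, were among the 12 furthest higher. The lower genes also held Sectm1b, which binds CD7, at 0.297 against 110.5 CPM, the small heat shock protein Hspb1 at 11.5 against 170.3 and the protease gene Tmprss6 at 22.1 against 269.98. Dmd, Bst1, Dsc2, Anxa8 and Acpp completed them. Krt17, Sectm1b, Ccl2, Dmd, Nos2, Hspb1, Bst1, Dsc2 and Acpp, and among list members Plk1, Ciita, Muc1, Il11, Ibsp, Cxcl10 and Icam1, were under 5 CPM in the median tumour cell of both groups, so a minority of cells carried their sums.

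The fat pad tumour against culture asked which differences from culture were also seen outside bone. H2-Eb1 stood at 1329 CPM and H2-Ab1 at 1241 CPM in the fat pad, with no count in culture, and Cd74 at 2509 against 5.93. Fos stood at 6860.3 CPM against 17.6, near the 6936 CPM of bone at day 4. Lcn2, an iron-binding protein of inflamed tissue, was at 2089 CPM against 13.1, and Cxcl1 at 2221 against 265. Rrm2 was at 30.0 CPM against 519 and Psat1 at 23.7 against 533.

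MHC class II (5.31), immediate early (2.44), MHC class I (1.92), dormancy (1.21), TGF-beta response (1.10) and inflammatory (0.97) lists were furthest higher in the fat pad. The class II median, set against members without a count in culture, ran from 3.65 with a pseudocount of 20 CPM to 7.55 with 1 CPM. Psmb9 stood at 306 against 38.4 CPM, Btg2, which slows the cell cycle, at 284 against 2.77 and Ltbp3 at 367 against 32.7. Bone (0.86), epithelial (0.73), glycolysis and hypoxia (0.57), mesenchymal (0.44), ribosomal protein (0.38) and mitochondrially encoded (0.76) lists were higher too. Spp1 stood at 9018 against 579.8 CPM, Epcam at 1409 against 201 and Car9 at 151 against 10.4. S phase (−1.91), G2 and M phase (−1.64), serine supply (−1.11), interferon (−0.79) and cholesterol (−0.49) lists were lower, with Ccna2, an S phase and mitotic cyclin, at 58.2 against 402 CPM and Oasl1 at 45.5 against 252. Of 13 planned settings mesenchymal and ribosomal protein lists stood apart in 11, and bone, glycolysis, cholesterol, inflammatory and mitochondrially encoded lists in 12. Unlike the fat pad, 4T1 bone at day 4 had epithelial genes below culture, at −0.77.

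Cultured 4T1.2 against cultured 4T1 asked how the lines differed before injection. Mmp3, on chromosome 9 (7445822 to 7455975), stood at 1421 CPM (1415 to 1426) in 4T1.2 and 30.5 CPM (29.7 to 31.3) in 4T1. Gpnmb, a membrane glycoprotein of bone and pigment cells, was at 295 CPM against 6.16, and the fructose transporter gene Slc2a5 at 78.7 against 0.719. Epcam and Cdh1, adhesion molecules of epithelium, were at 0.973 and 1.51 CPM in 4T1.2 against 201 and 238 in 4T1. The keratin genes Krt14 and Krt19 were at 2.78 and 1.21 CPM against 384 and 227. Il1a was at 0.951 CPM against 167.

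Epithelial genes had a median of −2.10, with 21 of 29 at least 2-fold lower in 4T1.2. Inflammatory genes stood at −0.97, with the chemokine gene Cxcl16 at 26.9 against 195 CPM, and TGF-beta response genes at −0.53, with Thbs1 at 57.7 against 505. Cholesterol (−0.35), interferon (−0.17) and ribosomal protein (−0.10) lists were also lower, with Fdft1, the squalene synthase, at 20.7 against 64.1 CPM and Mx2 at 23.0 against 69.2. Oxidative stress (0.35) and integrated stress response (0.31) lists were higher, with the cystine carrier gene Slc7a11 at 36.1 against 6.64 CPM and the chaperone gene Hspa5 at 4225 against 1981. The ribosomal protein list stood apart in 11 of 13 planned settings, and integrated stress response and cholesterol lists in 12. Lcn2, Arhgdib, Itgb7, the nerve growth factor receptor Ngfr, Ckb and Plvap were further genes higher in 4T1.2, with log2 ratios between 3.24 and 3.79. Sfn, Cldn7, Mal, Inhba, Cldn4 and Lamb3, most of them epithelial, were further lower genes, Sfn at 1.21 against 164 CPM.

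Etv5, Senp2 and Tmem41a, 3 of the genes furthest higher in 4T1.2 culture, lie within 10 Mb of chromosome 16. Etv5 is an ETS transcription factor at 266 against 20.9 CPM, Senp2 (22009484 to 22049269) removes SUMO from proteins and was at 687 against 61.4, and Tmem41a (21934326 to 21947552) was at 215 against 17.8. The chaperone gene Dnajb11 (22857845 to 22879634), at 1181 against 126 CPM, and Sdf2l1, at 240.4 against 52.9, both of the integrated stress response list, lie there too. Between 15 and 25 Mb, a segment chosen after the values were seen, 68 genes had a median log2 ratio of 1.54 in culture and 69 genes 1.29 at day 4. At least 1.5-fold higher in 4T1.2 culture were 54 of the segment's genes, or 79.4%, against 11.7% of other genes. The 8 measured genes from Dgcr2 to Trmt2a within it had medians of 0.0127 in culture and −0.22 at day 4.

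**Figure D4:**
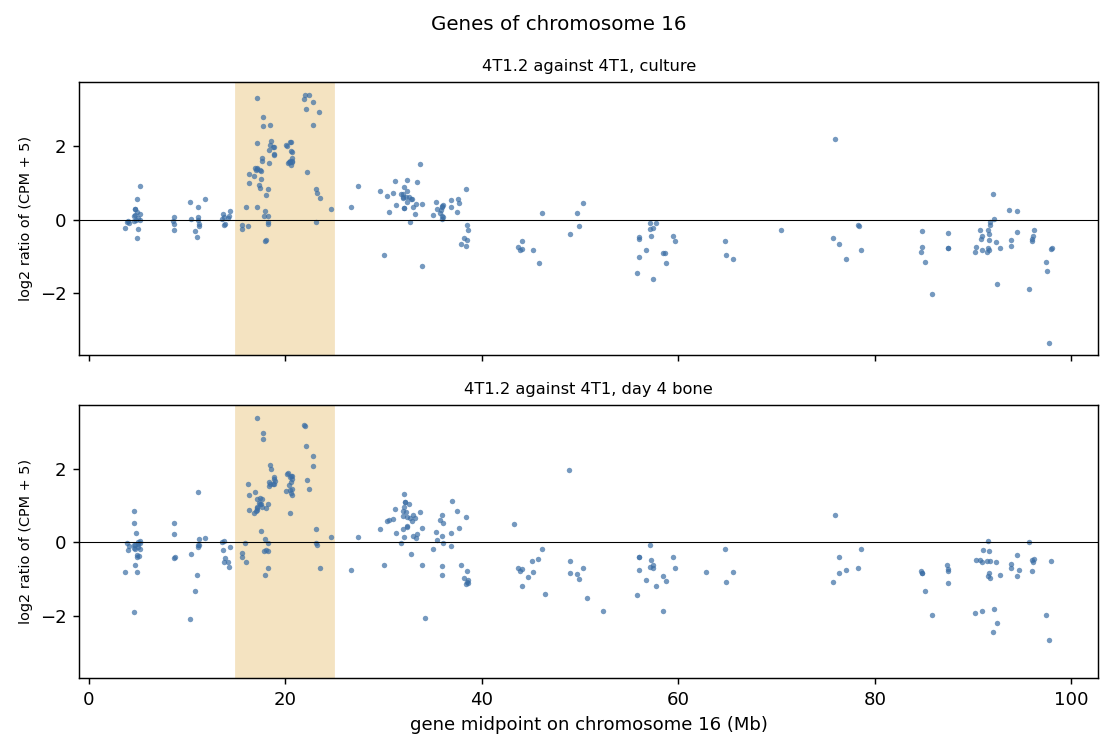
Log2 ratio of 4T1.2 over 4T1 for each gene along chromosome 16 in Mb (mm10), in culture and in bone at day 4. Genes between 15 and 25 Mb had medians of 1.54 in culture and 1.29 at day 4.

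4T1.2 bone at day 4 against 4T1 bone at day 4 asked whether the lines still differed in bone. The cluster with 52 of the 53 tumour cells of 4T1.2 also held 22 of the 140 of 4T1. The 4T1 sum therefore joins cells that clustered apart from and with 4T1.2. Sfn, an epithelial 14-3-3 protein on chromosome 4 (133600556 to 133602168), was at 0.190 CPM (0.129 to 0.270) in 4T1.2 and 212 CPM (210.2 to 213) in 4T1, and was detected in 5.77% and 95.6% of cells at equal depth. Without thinning it was also detected in 23.1% of host-like cells of 4T1.2 and 84.6% of those of 4T1. Epcam was at 0.0306 CPM against 68.3, and Krt14 at 11.8 against 223, but the median 4T1 cell held only 0.432 CPM of Epcam and 1.18 CPM of Krt14, against 0 CPM in 4T1.2. Ccl2 stood at 185 CPM in 4T1.2 against 16.7 in 4T1, Slc2a5 at 40.5 against 0.0179 and Mmp3 at 822 against 257. Ifit3, an antiviral interferon gene under 5 CPM in the median cell of both lines, was at 5.69 CPM against 70.8, and Nlrc5, which switches on MHC class I genes, at 9.07 against 47.1.

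Epithelial genes had a median of −1.87, interferon genes −1.16, MHC class I genes −1.05 and immediate early genes −0.79. Nr4a2 stood at 59.8 against 442 CPM and the stress-induced Atf3 at 219 against 994. TGF-beta response (−0.59), integrated stress response (−0.43), mesenchymal (−0.42), cholesterol (−0.39) and dormancy (−0.35) lists were lower as well, with Inhba, an activin subunit, at 3.90 against 64.8 CPM, Col6a1 at 15.0 against 124 and Sox9 at 136 against 456. Ribosomal protein genes alone were higher, at 0.05, but stood at −0.24 in higher-numbered cells, and no list was higher without mixed wells. Mesenchymal and dormancy lists stood apart in 10 of 12 planned settings, and integrated stress response, immediate early, cholesterol and ribosomal protein lists in 11. Tmem41a, Senp2, Scarf2 and Klhl22 of the chromosome 16 segment had log2 ratios between 2.80 and 3.18. The blood genes Hbb-bs, Hba-a1, Ighm, Hba-a2 and Cd79b filled 5 of the 12 higher places, and without mixed wells Hbb-bs went from 3.93 to −0.33 and Hba-a1 from 3.75 to −0.65. In the median cell Hbb-bs and Hba-a1 were lower in 4T1.2, and Hba-a2 was under 5 CPM in both lines. Xlr, a lymphoid-regulated gene at 33.8 against 0.244 CPM, was the remaining one. The reporter luciGFP was at 74.4 against 159 CPM in the sums, but its median per tumour cell was 65.0 CPM in 4T1.2 and 60.1 CPM in 4T1, and its log2 ratio of −1.05 became 0.16 in higher-numbered cells. Among the lower genes were also Tmprss11e, Krt19, Lmo1, Cldn7, Perp, Flt1 and Lad1, with Flt1, a VEGF receptor, at 4.49 against 91.3 CPM.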

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

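The values here were listed by fixed rules, and the tests of mCherry, of cross-talk and of host cells in tumour wells were chosen only after these patterns were seen.

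MHC class I genes differed between the lines in the same contrast: the median log2 ratio of day 4 bone against culture was 0.51 in 4T1 and −0.51 in 4T1.2, a difference of 1.01 that was not tested. In higher-numbered cells the 4T1.2 list, at −0.41, did not stand apart. Psmb9 stood at 92.3 CPM in 4T1 in bone against 38.4 in culture, whereas B2m stood at 1006 CPM in 4T1.2 in bone against 3060.2. Genes of the integrated stress response also differed, with medians of 0.30 in 4T1 and −0.43 in 4T1.2 and a difference of 0.73, likewise not tested. In higher-numbered cells the 4T1 list, at 0.13, did not stand apart. Ppp1r15a stood at 215 against 15.8 CPM in 4T1, and Chac1 at 12.3 against 79.4 in 4T1.2.

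mCherry RNA appeared in cells outside the comparisons, the host-like cells, with medians of 1920 CPM in 4T1 at day 4, 290.04 at day 10, 179.9 at day 16, 206 in 4T1.2 at day 4 and 13.2 in the fat pad. Its presence was selected for, since wells with an mCherry Ct above 30 had been discarded. In 4T1 at day 4, the only group tested, RNA of tumour cells in the same wells is argued against, since Krt8 and Krt18 per mCherry in host-like cells reached 0.0884% of the tumour ratio. Cross-talk from tumour libraries is argued against because the host-like median was 463% of the tumour median, while luciGFP stood at 1.03%, and so is a fixed amount of template per well, because mCherry per ERCC count differed 5.56-fold between the wells with the lowest and the highest ERCC share while mCherry CPM spread 1.45-fold. In the fat pad the host-like median was 2.22% of the tumour median, so cross-talk stays open there, and in 4T1.2 at day 4 it was 61.2%. Transfer of mCherry RNA or labelled material into host cells stays open, no biological explanation was tested, and neither the mCherry gate nor qPCR at Ct 30 had removed these cells.

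Blood-cell genes such as S100a8, Lyz2 and Hbb-bs stood among the genes furthest higher in tumour cells from bone. In the 125 tumour wells of 4T1 at day 4 left without the 15 mixed ones, 36 of 38 host markers, or 94.7%, lay within 2-fold of 1.34% of the group's own pool, which is what cross-talk between libraries or free RNA in every well would give. Over all 140 wells of that group an equal share of the pool is argued against as the whole cause. Neutrophil markers stood at 3.53% and erythroid markers at 1.19%, 2.96-fold apart, with Camp at 5.46% and Csf1r at 26.9%. In 4T1.2 at day 4 the classes lay close together over all tumour wells. Neutrophil markers stood at 14.2%, monocyte or macrophage markers at 12.9%, erythroid markers at 13.8% and B-cell markers at 12.5%. The class medians therefore decide nothing in 4T1.2. Whole host cells in tumour wells stay open. In mixed wells of 4T1 day 4 the host class most enriched over the pool exceeded the second by 2.79-fold in the median well. The others had 1.22-fold. This was short of the 3-fold set before the value was seen, a mark set for that group alone. The same ratio was 6.11 in 11 mixed wells of day 10, 2.38 in 6 of day 16 and 3.13 in 30 of 4T1.2 day 4. In the other wells of those groups it was 1.47, 1.36 and 1.18. Mixed wells were picked by blood-cell genes, and the subtracted cross-talk was set by host markers. The fall of such genes under either step therefore tests nothing. A gate on CD45, whose effect was not measured here, would address blood cells other than erythroid ones, but not cross-talk.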

How the results depend on the processing

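All settings that leave out mixed wells, subtract cross-talk or name clusters by another rule, and their tests, were chosen only after the data were seen. Of 114 lists that stood apart, 58 did so under every planned setting and 56 were lost under at least 1. Kept in every setting were the immediate early and TGF-beta lists of both lines at day 4 against culture, from 1.74 to 2.52 for the former in 4T1, interferon genes from −2.31 to −1.27 in 4T1.2, and MHC class II genes from 2.598 to 4.97 at day 16 against day 4. S phase and G2 and M phase genes at day 16 kept −2.68 to −1.49 and −3.11 to −2.03. Epithelial genes of 4T1.2 kept −2.57 to −1.10 in culture. A list median stayed when it kept its side of the random lists, whatever its size, and a gene's log2 ratio when it lay within the limits of both Poisson intervals, which cover counting alone. Over planned settings 1827 list medians stayed, 102 moved and 18 reversed, and for named genes 492 stayed, 1030 moved and 2 reversed. Of list counts, held to 1.5-fold, 189 stayed and 7 moved, of host-like shares, held to their binomial intervals like detection shares, 21 stayed, and of detection shares 37 stayed and 83 moved when cells were not thinned. For each value below the cause was not tested, unless the setting itself shows it.

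With host-like cells included, which adds blood cells by construction, 4T1.2 day 4 against culture had 5 lists higher, MHC class I at 0.0477, bone genes at −0.0800 and ribosomal proteins at −0.21. In that setting day 16 against fat pad had 5 lists lower, S phase at 0.13, MHC class II at 0.60 and inflammatory genes at 0.59, inflammatory genes of day 10 against day 4 stood at 0.19, and ribosomal proteins of 4T1.2 against 4T1 at day 4 at −0.0345. Without a cell filter G2 and M phase of 4T1.2 day 4 against culture stood at −0.0408, and 4T1.2 against 4T1 at day 4 had 2 lists higher and ribosomal proteins at −0.0256. In lower-numbered cells G2 and M phase of 4T1.2 day 4 against culture stood at −0.10, dormancy and ribosomal lists of day 10 against day 4 at −0.0318 and 0.0470, and ribosomal proteins of the cultures at 0.00146. In higher-numbered cells day 10 against day 4 had 3 lists lower, day 16 against fat pad 4 higher with integrated stress response at −0.10, the cultures 1 higher, Cldn4 of day 16 against day 4 stood at −2.23, and in 4T1.2 against 4T1 at day 4 ribosomal proteins stood at −0.24 and luciGFP at 0.16. With no minimum on members day 10 against day 4 had 3 lists lower and bone genes at −0.00129. Without Ptprc-positive cells, hypoxia genes of fat pad against culture stood at −0.0652, with 15 fat pad cells left. That setting was not run for bone groups, where at most 1 cell was left.

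Without mixed wells, and also after subtraction, day 10 against day 4 had 3 lists lower and 4T1.2 against 4T1 at day 4 had 0 higher. Without them alone Hbb-bs, Hba-a1 and Hba-a2 in the latter went to −0.33, −0.65 and −0.16. After subtraction Hba-a2 stood at −0.20, S100a8 and Camp of 4T1 day 4 against culture at −0.0761 and −0.00164, and for day 16 against fat pad S100a8, S100a9, Camp, Retnlg and Ifitm6 at −0.27, −0.15, −0.00847, −0.00251 and −0.22. The lines' Pearson r and Spearman rho became 0.506 and 0.415, and rho 0.476 with cells weighted equally. The first and second naming rules gave host-like shares of 65.5% and 76.2% in 4T1 day 4 and 63.8% and 99.6% in 4T1.2 day 4.

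No paired analysis was possible because the labels link no cells between groups. What the cell numbers stand for is not stated, although lower-numbered and higher-numbered cells differed in places, as for Epcam and Cldn4 at day 16. Depth sets which genes near 0 are seen, and H2-Ab1 was found in 99.3% of unthinned 4T1 day 4 tumour cells at a median of 2.84 CPM.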

Other observations

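All tests of chromosome 16 were chosen only after the result was seen.

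Genes of chromosome 16 between 15 and 25 Mb, among them Senp2, Tmem41a, Dnajb11, Etv5 and Igf2bp2, stood higher in 4T1.2 than in 4T1, with a median log2 ratio of 1.54 over 68 genes in culture and 1.29 over 69 genes in the separate day 4 libraries. A few strongly changed genes are argued against, since 79.4% of the segment's genes were at least 1.5-fold higher in culture and 75.4% at day 4. A gain of the whole segment's DNA in 4T1.2 is argued against, since the run of 8 measured genes from Dgcr2 to Trmt2a had medians of 0.0127 in culture and −0.22 at day 4. A gain of parts of it remains a candidate explanation, as the segment's genes of low, middle and high expression had day 4 medians of 1.07, 1.18 and 1.58, shared regulation of neighbouring genes was not tested, and DNA was not analysed here.

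Elsewhere the median log2 ratio of 4T1.2 over 4T1 in culture was −0.56 for genes of chromosome 8, −0.42 for chromosome 19, 0.40 for chromosome 18 and 0.38 for chromosome 6. At day 4 the values were −0.72, −0.44, 0.25 and 0.05. Over 306 windows of 5 Mb the medians of culture and day 4 had a Pearson r of 0.830, where neighbouring windows are not independent. In culture 17 windows stood so high that at most 1 of 2000 matched random draws reached them, and 9 of these lay above the middle 95% of draws at day 4. Likewise 24 stood so low, and 22 of these lay below that range at day 4.

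In 4T1 at day 16 the cluster with high Epcam and Cldn4 held 23 lower-numbered and 0 higher-numbered cells, whereas the same cluster held 39 lower-numbered and 33 higher-numbered fat pad cells. A group of 12 cells, 10 of them from 4T1 day 4 bone, was led by Cxcl10, Cxcl11, Rsad2 and Ifit3, which are interferon targets. MHC class II genes summed per tumour cell had medians of 19.9 CPM at day 4, 2734 at day 10, 2868 at day 16 and 5698 in the fat pad.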
